A study of Mus musculus with 2 samples.

How the data were processed

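RNA from the midbrain of E12.5 mouse embryos (strain B6NCrl, mixed sex) was sequenced in 2 libraries, which form 1 group. Per the labels, each library came from a separate pool of embryos, 120 in replicate 1 and 88 in replicate 2, and was made from 10 ng of RNA longer than 200 nt that had been extracted with mirVana. The protocol field links the manual of a SMARTer Ultra Low RNA kit, a kit type that primes from poly(A) tails, and the libraries were labelled total RNA. Spike-in RNAs had been added.

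The deposited expected counts are estimated counts per gene and per transcript that need not be whole, per the file headers, with the columns of an RSEM output. The deposited TPM values are abundances that the authors normalised to effective length and library. A posterior mean TPM stood beside them, per the file headers. The deposited isoform percent is the share of a gene's abundance given to each transcript. The annotation was GENCODE M4 on mm10, and the aligner and its version are not given in the sources used here. Effective length was the annotated length minus 99 for each transcript. Gene names, classes and coordinates came from GENCODE M21 on the same assembly, in which 42462 of 43346 gene identifiers matched without their version. The 884 unmatched genes held 0.293% and 0.284% of all counts, spike-ins included. Spike-ins and 26248 short numbered features were left out of library sizes and tests. The list members Ahsp, Rmst, Sox2ot and Snhg1 had no measured gene under that name and were not analysed here.

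Expected counts were rounded to whole numbers for tests. TMM factors from edgeR 4.0.16 (R 4.3.3) were 0.995 and 1.005. The biological coefficient of variation came from edgeR with an intercept only. For each gene with at least 10 counts summed, a two-sided exact binomial test compared the 2 libraries, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, a ratio of at least 1.5-fold and a mean TPM of at least 1. Log2 ratios had 0.5 counts added in each library. Such a test compares these libraries and not conditions. In the closing section, genes at 0 counts in a library were set to a floor of 3 counts per library. Intervals of ratios are 95% exact binomial intervals. These intervals and floors cover counting error only, while the deposited TPM intervals also cover how reads were divided among similar genes. A deposited TPM interval need not contain the deposited TPM. In replicate 1, Tcf7l2 was at 443.67 TPM with an interval of 421.98 to 439.35 TPM.

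Levels are deposited TPM with the SD over the 2 libraries, and list levels are medians over members of log2(TPM + 1) or of TPM. The shift of a list was the median log2 ratio of its members at a mean TPM of at least 1, for lists with at least 4 such members. It was set against 10000 random lists of the same size drawn within 20 bins of mean expression, and the percentile is a description with no p-value. With 1 group of 2 libraries there was no contrast between conditions.

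The 30 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule took, in each list, the 4 members with the highest mean TPM and those under 1 TPM in both libraries (named or counted). It took every member of the midbrain and isthmus, forebrain, hindbrain, dopaminergic, GABAergic, glutamatergic and Y-linked lists, with Xist. It also took the 10 most abundant nuclear protein-coding genes, and the 10 genes with the largest ratio in each direction among called genes at a mean TPM of at least 5. A few genes that the rule takes are not reported here by name, and they remain in the list medians and counts. Isoforms were named for the panel genes whose top isoform differed and for the 6 most abundant panel genes. Other genes named below were chosen after their values were seen.

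The steps were tested on simulated data. With 18939 genes and counting error only, the binomial calls recovered 94% of genes changed 2-fold and 98% of those changed 4-fold, and called 0 unchanged genes. With the overdispersion estimated from these libraries and no gene changed, the same rule called 186 genes. In simulated lists of 12 unshifted genes, 6% fell outside the middle 95% of matched random lists. The simulated genes varied independently, so this share does not hold for lists whose members move together. A simulated coefficient of variation of 0.2 was estimated as 0.201. Alternatives were other size factors (DESeq2 1.42.0 or total counts), count and TPM thresholds, pseudocounts, posterior mean TPM, TPM rescaled over nuclear protein-coding genes, TMM-scaled CPM, a negative binomial exact test of edgeR, and leaving out each library. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.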

Results

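Gene expression was measured in the midbrain of E12.5 mouse embryos, a stage at which progenitors divide beside newly formed neurons. The 2 libraries came from separate pools of 120 and 88 embryos of mixed sex. Replicate 1 held 29430493 estimated counts and replicate 2 held 37381984, of which 28212923 and 36082643 fell on genes. Spike-in RNAs took 4.14% and 3.48% of the counts. The labels name 1 tissue and 1 stage, so the comparisons are between gene groups within the tissue and between the 2 pools.

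Most expressed genes were detected in both pools. At 1 TPM or more in both libraries, 14895 genes were detected, of which 13006 were protein-coding, and 1159 genes reached 1 TPM in 1 library only. The most abundant nuclear protein-coding genes were Tuba1a, a tubulin of young neurons, at 8590 ± 309 TPM (SD, n = 2), the embryonic globin gene Hbb-y at 6772 ± 592 TPM and Hba-a2 at 5537 ± 756 TPM. They were followed by Tmsb4x, Actb, Ftl1, Hist1h2ap, Stmn1, Tmsb10 and Ppia. Across 43346 genes, log2(TPM + 1) correlated between the libraries with a Pearson r of 0.994 and a Spearman rho of 0.952, where genes are not independent replicates. The edgeR biological coefficient of variation was 0.0939 for genes and 0.0334 for spike-ins. At a mean count of at least 1000 it was 0.0643 for genes and 0.0296 for spike-ins. The libraries differed by more than counting error, with a mean chi-square per gene of 8.80 and a median of 1.75.

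**Figure D1:**
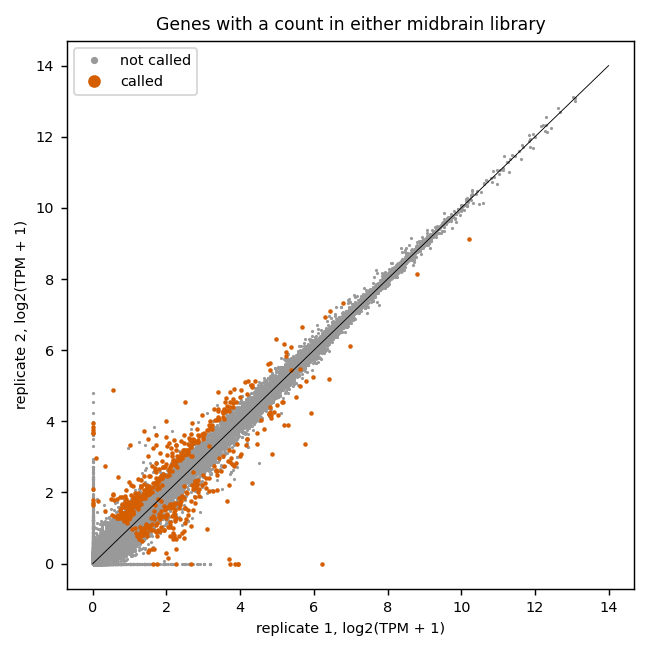
Log2(TPM + 1) of each gene with a count in replicate 2 (vertical axis) against replicate 1 (horizontal axis), with the 539 genes called between the libraries in orange. Most genes lie on the diagonal, and the Pearson r over genes is 0.994.

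Midbrain transcription factors were expressed and Hox genes of the hindbrain and spinal cord were near 0. Otx2, a transcription factor of the forebrain and midbrain (chromosome 14, 48657677 to 48673819 in mm10), was at 144.2 ± 3.37 TPM (SD, n = 2). Cnpy1, an isthmus gene, was at 99.6 ± 31.1 TPM, Meis2 at 68.6 ± 10.5 TPM, Pax3 at 47.1 ± 5.59 TPM and Dmbx1 at 14.9 ± 0.304 TPM. The isthmus signals Fgf17 and Fgf8 were at 8.71 ± 3.36 and 4.07 ± 0.728 TPM, and Wnt1 at 8.86 ± 2.39 TPM. En1 was at 7.20 ± 1.83 TPM, Pax5 at 6.51 ± 2.31 TPM, Pax7 at 4.12 ± 0.799 TPM, Lmx1b at 2.07 ± 0.368 TPM and En2 at 1.47 ± 0.375 TPM, while Pax2 was under 1 TPM in both libraries. Of the 14 genes in the hindbrain list, 13 were under 1 TPM in both libraries, and the exception Gbx2 was at 28.2 ± 5.02 TPM. Those under 1 TPM included Hoxa2, Hoxa3, Hoxa5, Hoxb1, Hoxb2, Hoxb3, Hoxb4, Hoxb5, Hoxc4, Hoxd3, Hoxd4 and Egr2.

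Most forebrain transcription factors of the list were detected as well. Lhx2 was at 98.9 ± 11.3 TPM (SD, n = 2), Dlx1 at 39.4 ± 12.4 TPM, Six3 at 18.3 ± 2.79 TPM, Emx2 at 17.0 ± 3.04 TPM, Dlx5 at 15.4 ± 3.32 TPM and Dlx2 at 15.2 ± 3.00 TPM. Nkx2-1, Emx1, Tbr1 and Rax lay between 1.96 and 5.89 TPM, and Hesx1 and Six6 were under 1 TPM in both libraries. The median of the midbrain and isthmus list minus that of the forebrain list was -0.81 on the log2 scale in replicate 1 and 0.18 in replicate 2, so its sign differed between the libraries, and it was -0.91 over members at 1 TPM or more. Against the hindbrain list the difference was 2.95 ± 0.26 (SD, n = 2), or 5.55 with a pseudocount of 0.1. Over members at 1 TPM or more it took the other sign, at -1.80. There Gbx2 was the only member of the hindbrain list, so that value rests on Gbx2 alone on the hindbrain side. No p-value is given for these differences, which rest on 2 libraries.

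Dividing progenitors and young neurons were both abundant and mature glia were scarce. The cell division list had a median of 146.6 ± 3.41 TPM (SD, n = 2), led by Top2a, Cdk1, Ccnb1 and Ccnd1 at 218.1 to 249.9 TPM. The postmitotic neuron list had a median of 138.6 ± 3.75 TPM, led by the neuronal tubulin Tubb3 at 917.9 ± 16.5 TPM, Stmn2, Ina and Map2. Radial glia genes had a median of 62.5 ± 1.42 TPM, with Vim at 980.1 ± 20.96 TPM, Fabp7 at 873.6 ± 57.4 TPM, Hes5 at 679.9 ± 52.5 TPM and Msi1 at 178.0 ± 5.83 TPM. Proneural and commitment genes had a median of 68.7 ± 0.103 TPM, with Hes6 at 361.7 ± 19.6 TPM, Gadd45g, Btg2 and Neurog2. The glia list had a median of 2.53 ± 0.735 TPM, led by Mbp, Pdgfra, Aldh1l1 and Olig2, and 5 of its 12 members, Gfap among them, were under 1 TPM in both libraries. The cell division minus neuron difference was 0.07 ± 0.01 on the log2 scale and took the other sign without length normalisation, at -0.14.

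GABAergic and glutamatergic genes were expressed, dopaminergic genes were lower, and serotonergic and cranial motor genes were mostly under 1 TPM. Among GABAergic genes, the selector factor Gata3 was at 65.8 ± 2.77 TPM (SD, n = 2), the synthesis enzyme Gad2 at 48.1 ± 5.81 TPM, Tal2 at 34.6 ± 2.76 TPM, Sox14 at 34.2 ± 2.40 TPM, Helt at 25.4 ± 4.61 TPM and Gata2 at 23.0 ± 0.764 TPM. Gad1 was at 21.7 ± 0.0141 TPM, Tal1 at 7.88 ± 0.304 TPM and Slc32a1 at 3.04 ± 0.573 TPM. The small SD of Gad1 holds for TPM only, since its normalised count in replicate 2 was 0.872 of that in replicate 1. Among glutamatergic genes, Pou4f1 was at 86.1 ± 5.93 TPM, Lhx9 at 78.8 ± 8.15 TPM, the vesicular transporter Slc17a6 at 42.3 ± 2.42 TPM, Barhl1 at 32.6 ± 7.97 TPM and Pou4f2 at 3.16 ± 0.0354 TPM, while Slc17a7 and Slc17a8 were under 1 TPM. The glutamatergic minus GABAergic median was 0.74 on the log2 scale in replicate 1 and -0.08 in replicate 2. Among dopaminergic genes, Nr4a2 was at 27.2 ± 2.69 TPM, Ddc at 18.4 ± 4.63 TPM, Th, which makes the dopamine precursor, at 18.3 ± 7.38 TPM and Slc18a2 at 13.3 ± 2.62 TPM. Pitx3 was at 3.29 ± 0.0283 TPM, Ret at 1.94 ± 0.495 TPM and Drd2 at 1.41 ± 0.184 TPM, and Slc6a3 and Aldh1a1 were under 1 TPM. Floor plate genes had a median of 7.08 ± 3.56 TPM, with Msx1, Wnt5a, Lmx1a and Foxa2 highest. Serotonergic genes had a median of 0.490 ± 0.0919 TPM, with only Gchfr, which is not specific to these neurons, over 1 TPM, and Slc6a4, Tph2 and Fev below it. The motor and cholinergic list had a median of 0.670 ± 0.339 TPM, with Isl1 at 24.3 ± 9.93 TPM, then Slc5a7 and Slc18a3, and 4 of its 7 members under 1 TPM in both libraries.

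**Figure D2:**
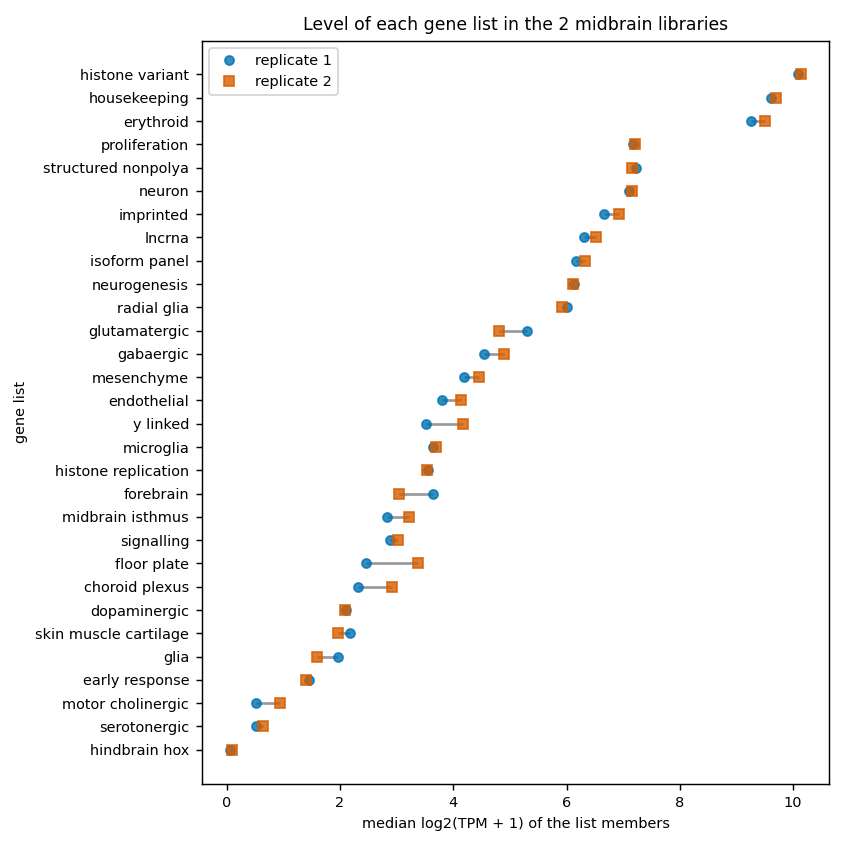
Median log2(TPM + 1) of the members of each of the 30 gene lists (horizontal axis) in replicate 1 (circles) and replicate 2 (squares). Histone variants and housekeeping genes lie at the top, and the hindbrain and Hox list lies at the bottom.

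Blood, vessel, connective tissue and macrophage genes were all present in the dissected tissue. Red cell genes had a median of 684.1 ± 86.2 TPM (SD, n = 2), with Hbb-y, Hba-a2, Hba-a1 and Hba-x highest. Mesenchymal genes had a median of 19.1 ± 2.70 TPM, with the collagens Col3a1 at 483.7 ± 120.0 TPM and Col1a1 at 397.7 ± 101.1 TPM, then Col1a2 and Lum. Endothelial genes had a median of 14.8 ± 2.63 TPM, with Egfl7, Cldn5, Kdr and Esam highest. Microglia and macrophage genes had a median of 11.7 ± 0.311 TPM, with C1qb, Fcer1g, Tyrobp and C1qc highest. The skin, muscle and cartilage list had a median of 3.20 ± 0.417 TPM, with Col2a1, Tnnt1, Krt15 and Krt5 highest and 5 of 13 members under 1 TPM. Choroid plexus genes had a median of 5.26 ± 1.78 TPM, with Ttr at 26.2 ± 17.6 TPM, Folr1, Aqp1 and Kcne2, and Kl under 1 TPM.

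Transcripts of replication-dependent histone genes were measured far below those of histone variants. The replication-dependent list had a median of 10.7 ± 0.152 TPM (SD, n = 2), with Hist1h4d, Hist1h2ae, Hist1h1e and Hist1h2ab highest, and the variant list had a median of 1242 ± 24.5 TPM, with H3f3a, H2afz, H3f3b and H2afv highest. The difference was 6.57 ± 0.05 on the log2 scale. Replication-dependent histone mRNAs lack a poly(A) tail and the priming of the libraries is not settled here, so this cannot be read as a difference in transcript level. Of 67 genes of the Hist family, 5 had a mean of at least 100 TPM, and Hist1h2ap alone, at 4149 ± 239.8 TPM, held 72.5% of the family's TPM. Structured RNAs without a poly(A) tail had a median of 179.5 ± 11.9 TPM. The 7SL copies Rn7s2 and Rn7s1 were at 8712 ± 3.74 and 8437 ± 384.3 TPM and are near-identical, Rn7sk was at 285.2 ± 25.0 TPM and Rpph1 at 73.8 ± 1.28 TPM. Of all counts, spike-ins included, protein-coding genes held 92.0 ± 0.577%, the mitochondrial genome 1.05 ± 0.151% and long noncoding RNAs 2.12 ± 0.0525%. Spike-ins took 4.14% and 3.48% of these counts in replicates 1 and 2, which enters these shares and their SD.

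Among long noncoding RNAs the median was 86.4 ± 6.86 TPM (SD, n = 2), with Malat1 at 6547 ± 56.3 TPM, Meg3, Gas5 and Pantr1. Imprinted genes had a median of 115.4 ± 18.8 TPM, with Nnat at 3532 ± 277.5 TPM, Cdkn1c, Mest and Meg3. Signalling genes of the FGF, WNT and SHH pathways had a median of 6.78 ± 0.559 TPM, with Lef1, Spry2, Axin2 and Dusp6 highest. Housekeeping genes had a median of 812.1 ± 30.0 TPM, with Actb, Ppia, Eef1a1 and Gapdh highest. Early-response genes had a median of 1.69 ± 0.0566 TPM, with Jun, Ier2, Dusp1 and Junb highest, and Npas4, Fosb and Hspa1b under 1 TPM.

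Between the pools, several forebrain genes were lower in replicate 2, and some isthmus, floor plate and Y-linked genes were higher. Pax6, a progenitor and diencephalic transcription factor, was 3.37-fold lower in replicate 2 (60.02 against 17.7 TPM, exact binomial test, adjusted p = 2.18e-232). Among forebrain genes, Tbr1, Emx1, Nkx2-1 and Dlx1 were called lower, and over the whole list 5 were called lower, 1 higher and 8 were not called. Some genes not called still differed by more than counting error, the only error the exact binomial test covers. Across genes at a mean count of at least 1000, the log2 ratios between the libraries had an SD of 0.141. Lhx2, Emx2, Six3, Dlx2 and Dlx5 were lower by less than 1.5-fold, each with an adjusted p under 0.05 (exact binomial test). Rax was higher, with an adjusted p of 0.109 in the same test. Among midbrain and isthmus genes, Fgf17 was 1.71-fold and Cnpy1 1.51-fold higher in replicate 2, and Wnt1 and Fgf8 were called lower, Fgf8 with overlapping TPM intervals, with 10 of 14 not called. Foxa2, Corin and Ferd3l of the floor plate and Th of the dopaminergic list were called higher, Corin by 2.95-fold and Th by 1.76-fold, with 5 of 8 floor plate and 8 of 9 dopaminergic genes not called. Among Y-linked genes, Ddx3y, Kdm5d and Uty were called higher, and Eif2s3y stood at 32.9 and 42.8 TPM without passing the 1.5-fold threshold. Xist, the RNA that silences an X chromosome in female cells, was at 29.4 TPM in replicate 1 and 18.1 TPM in replicate 2 (exact binomial test, adjusted p = 5.55e-206).

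**Figure D3:**
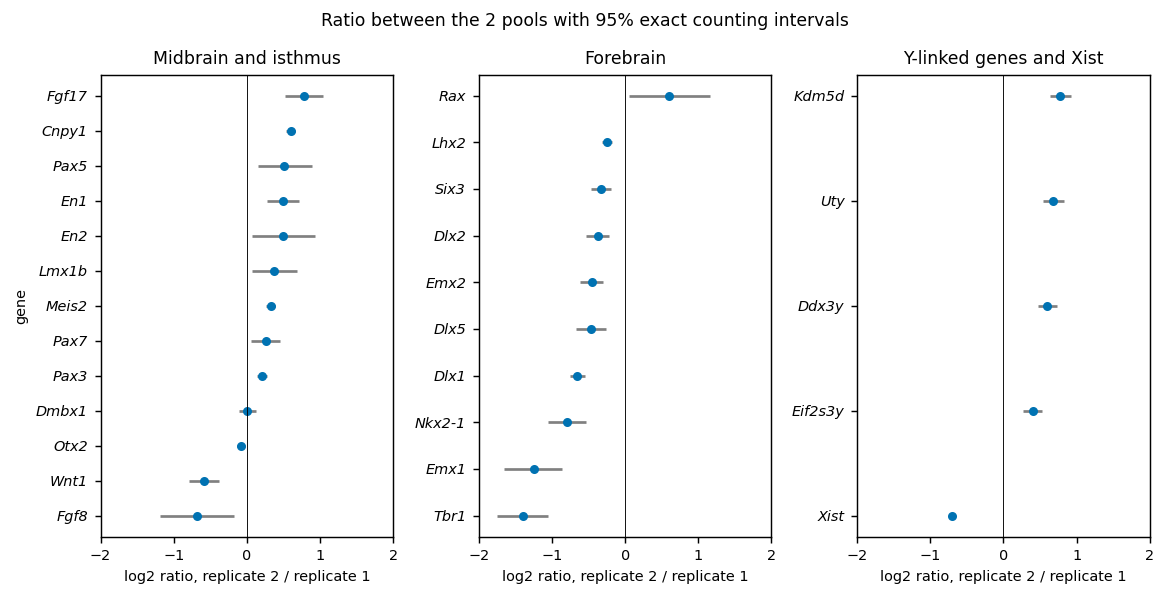
Log2 ratio of replicate 2 over replicate 1 (horizontal axis) for the named genes at a mean of at least 1 TPM in the midbrain and isthmus list, the forebrain list, and the Y-linked list with Xist. Lines are 95% exact intervals for counting error, and 9 of the 10 forebrain genes drawn lie below 0.

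In total, 539 of 15199 tested genes at a mean TPM of at least 1 were called, with 324 higher and 215 lower in replicate 2. At any ratio and TPM, 4319 of 18939 tested genes had an adjusted p under 0.05 in the exact binomial test. With the overdispersion between the libraries in the test (edgeR's exact negative binomial test), 201 genes were called, and 186 unchanged genes were called by the binomial rule in overdispersed simulated counts. Both used a common overdispersion estimated from these same 2 libraries, which includes any real difference between the pools. The 186 is therefore not an estimate of false calls among the 539. The deposited TPM intervals of the 2 libraries did not overlap for 287 of the called genes, a condition chosen after seeing the data. Of the 20 called genes at 5 TPM or more with the largest ratios, 16 had overlapping intervals, so no fold is given for them. Higher in replicate 2 among these were Gm12191, Gm9830, Rnu3b1, Rnu3b3, Gm14567, Zfp969, Gm24029 and Gm7879, and lower were mt-Nd4l, Gm15801, Rpl30-ps10, Rnu3b2, Rnu3b4, Gm14434, Duxbl3 and Gm20689. With intervals apart, Gm26735 was listed at 0 in replicate 1, with an interval up to 2.58 TPM, and at 12.4 TPM in replicate 2, with an interval from 8.34 TPM. Matn4, a cartilage matrix gene, was 4.62-fold higher in replicate 2. Afp, the fetal serum protein of yolk sac and liver, had 419 counts in replicate 1 and 4 in replicate 2, a ratio of 120.4-fold. Olig3, a diencephalic and spinal transcription factor, was 5.83-fold lower in replicate 2. The mt-Nd4l estimate of 256 counts in replicate 1 had a posterior SD of 120, so it is uncertain.

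As groups, 15 of the 27 lists that could be scored had a median ratio outside the middle 95% of matched random lists. The forebrain list had a median log2 ratio of -0.46, with 10 of 12 members lower in replicate 2, and the midbrain and isthmus list had 0.33, with 10 of 13 higher. Blood, vessel, connective tissue and macrophage lists were higher in replicate 2, with 0.21 for red cell genes, 0.22 for endothelium, 0.36 for mesenchyme, 0.36 for microglia and 0.40 for skin, muscle and cartilage. The Y-linked list had 0.64, floor plate 0.27 and dopaminergic genes 0.37. The neuron list had -0.10, glutamatergic genes -0.15, the isoform panel -0.11, structured RNAs -0.16 and choroid plexus genes -0.62. Of the 4 choroid plexus genes scored, 2 were higher and 2 lower in replicate 2, so their median is not a shift in 1 direction. Inside the range lay GABAergic genes at 0.02, radial glia at -0.04, cell division at 0.00, neurogenesis at -0.07, glia at -0.06, signalling at -0.02, replication histones at -0.03, variant histones at 0.04, long noncoding RNAs at -0.04, imprinted genes at -0.05, early-response genes at -0.03 and housekeeping genes at 0.01. Among the lists outside the range, the median level moved against the median ratio in the dopaminergic list, the neuron list, the skin, muscle and cartilage list, the choroid plexus list and the isoform panel list. The choroid plexus median changed sign, to 0.28, when its member under 1 TPM was added. Glutamatergic genes fell just inside the range with members down to 0.1 TPM, at -0.147, or after a regression on GC content and length, at -0.133, and structured RNAs did with deposited TPM, at -0.087, where the neuron list had -0.049, the isoform panel -0.052 and choroid plexus genes -0.34. These percentiles describe 2 libraries, and the hindbrain, serotonergic and motor lists had too few detected members. Random lists were drawn gene by gene, so their range does not cover members that move together. The isoform panel also shares members with the neuron list.

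**Figure D4:**
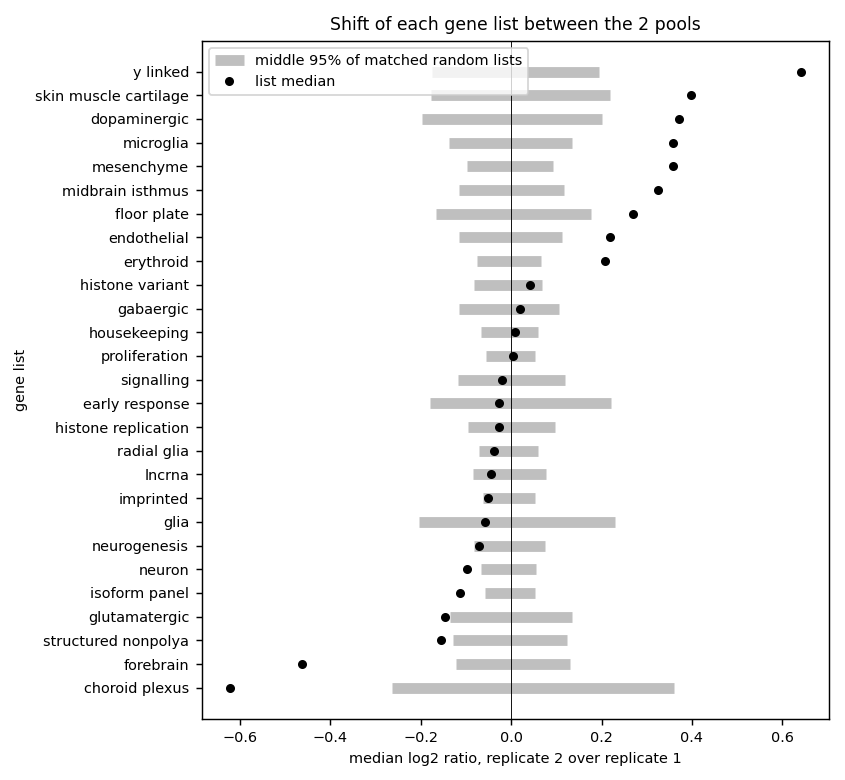
Median log2 ratio of replicate 2 over replicate 1 for each scored list (points, horizontal axis) with the middle 95% of medians of 10000 matched random lists (bars). The Y-linked list lies highest at 0.64 and the choroid plexus and forebrain lists lie lowest at -0.62 and -0.46. The choroid plexus point is the median of 4 genes, 2 higher and 2 lower in replicate 2.

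The most abundant isoform of a gene was mostly the same in both pools. Of 7056 genes at a mean TPM of at least 10 with 2 or more annotated transcripts, 6604 had the same top isoform, or 93.6%. The top isoform of the glycolytic enzyme gene Pkm (ENSMUST00000034834.11) held 82.9 ± 1.00% (SD, n = 2), that of Cdc42 (ENSMUST00000051477.8) 80.8 ± 1.48%, that of Stmn2 (ENSMUST00000029002.8) 94.5 ± 1.03% and that of Map2 (ENSMUST00000024639.7) 44.6 ± 1.29%. Ptbp2 had a single annotated transcript, and the top isoform of Ncam1 (ENSMUST00000193547.1) held 78.4 ± 2.70%. Where the top isoform differed, its median share was 38.5%, against 67.5% over all 7056 genes. In the panel it differed for Fgfr2, Pax6 and Fgf8. For Fgfr2 this was a near tie. ENSMUST00000117872.3 held 28.3% in replicate 1 and 26.1% in replicate 2, and ENSMUST00000124096.3 held 27.0% and 28.3%. For Pax6 the top isoform was ENSMUST00000090397.8 in replicate 1 (23.8%) and ENSMUST00000111087.5 in replicate 2 (24.1%). For Fgf8, which was at 4.07 TPM, it was ENSMUST00000111928.3 in replicate 1 (61.2%) and ENSMUST00000111924.3 in replicate 2 (35.1%).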

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

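Except for the regression on GC content and length and the condition on TPM intervals, which were chosen after seeing the data, the alternatives here were planned. Pearson's r was 0.986 with a pseudocount of 0.1 and 0.985 over genes at a mean TPM of at least 1, and the coefficient of variation was 0.0943 with total counts and 0.0941 without a count filter. The genes called between the pools numbered 214 at 2-fold (112 higher and 102 lower in replicate 2), 208 at a mean TPM of at least 5 (136 and 72) and 201 with edgeR's exact negative binomial test (108 and 93), the first 2 by construction. With deposited TPM intervals apart, 287 were called (176 and 111). The forebrain shift was -0.40 from deposited TPM, and the choroid plexus shift took the other sign, at 0.28, with members down to 0.1 TPM. Midbrain minus forebrain was -0.91 over members at 1 TPM or more. It ranged from -0.81 to 0.18 and glutamatergic minus GABAergic from -0.083 to 0.74 when either library was left out, so replicate 2 alone gave the other sign in each. Midbrain minus hindbrain was 5.55 with a pseudocount of 0.1 and 3.23 with rescaled TPM. It was -1.80 over members at 1 TPM or more, where Gbx2 was the only member of the hindbrain list. With CPM in place of TPM, cell division minus neuron was -0.14, radial glia minus neuron -0.25, neurogenesis minus neuron -1.10 and glia minus radial glia -4.84. With a pseudocount of 0.1, glia minus radial glia was -4.62, GABAergic minus dopaminergic 2.91, dopaminergic minus serotonergic 2.55 (1.68 with rescaled TPM) and red cell minus endothelial genes 5.49. As shares of all TPM, spike-ins included, protein-coding genes held 81.0%, the mitochondrial genome 2.31% and long noncoding RNAs 2.38%. Spike-ins held 10.178% and 8.515% of TPM in replicates 1 and 2. The top isoform was the same for 90.4% of genes at 1 TPM, 95.9% at 50 TPM and 99.4% where it held at least 60 percent. The cause was not tested unless stated. No paired analysis was possible because there was 1 group.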

Other observations

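The tests on the diencephalon, telencephalon and X-linked lists and the comparison with the neuron list were chosen only after the result was seen, while the regression on GC content and length and the tests on the hypothalamus and endoderm lists were written before their values were seen. The design names 1 group, so no biological explanation was tested, and the makeup of the pools was tested as a mixed sample. The diencephalon list was written once the forebrain shift was known. Whether its members mark the diencephalon alone, and not other forebrain tissue as well, was not tested. Of the 12 genes in this list, 5 were called lower in replicate 2, 0 were called higher and 7 were not called. Olig3 was 5.83-fold, Fezf1 6.25-fold and Fezf2 2.62-fold lower, Barhl2 1.85-fold and Tcf7l2 1.61-fold lower, and Dbx1, which was not called, was 1.05-fold higher.

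The forebrain list had a median ratio below 0 and the midbrain and isthmus list a median above 0 in replicate 2 over replicate 1, and each list had at least 1 member called the other way. Against a bias of GC content and gene length, the forebrain median stayed at -0.48 on the log2 scale after regression. Against dilution by blood or connective tissue, the forebrain median lay -0.36 from the neuron median (SD of the random medians 0.07). That SD comes from lists drawn gene by gene, so it does not cover members that move together. A candidate explanation is more diencephalon next to the midbrain in the tissue of replicate 1: the diencephalon list had a median of -0.39, or -0.37 without Olig3, below the range of matched random lists. The forebrain genes called lower with the largest ratios were Tbr1 at 2.63-fold and Emx1 at 2.38-fold. Both were in neither the diencephalon nor the telencephalon list, so the diencephalon median does not cover them. Hypothalamus and prethalamus genes, at -0.12, did not decide, since this is within 1 SD of the limit. With members down to 0.1 TPM their median was -0.37, below the range of matched random lists. Of these genes, Sim2 was called lower and 0 were called higher. Telencephalon genes, at -0.018, cannot be told apart from no shift or a mixed one, since Neurod6 and Neurod2 were called lower and 1 member higher. More of other forebrain tissue in replicate 1 is therefore left open beside the diencephalon.

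Of the Y-linked genes, Ddx3y, Kdm5d and Uty were called higher, and Xist was called lower, in replicate 2. A regression on GC content and length left the Y-linked median at 0.68, so this bias does not account for it. A larger share of male embryos in the pool of replicate 2 may account for it, since 6 X-linked genes that escape inactivation had a median of -0.13, below the range of matched random lists. The shift is small, as 0 of the 6 were called, and with deposited TPM it was -0.084, where Ddx3x and Pbdc1 were not lower. Eif2s3y differed less than the other Y-linked genes, at 1.32-fold.

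Afp was 120.4-fold higher in replicate 1, and its count had a posterior SD of 0% of the count, which argues against reads shared with a similar gene. Yolk sac or fetal liver tissue in the pool of replicate 1 may account for it: the other 9 endoderm genes with 10 or more counts were all lower in replicate 2, with a median of -2.30 on the log2 scale, or -2.20 with the 3 genes at 0 counts set to the floor. Of these, 2 were called, Apoa1 at 5.37 against 1.10 TPM and Apoa2 at 5.29 against 2.36 TPM. The liver gene Alb had 0 counts in both libraries, which argues against liver more than against yolk sac. Ttr, which the choroid plexus and yolk sac both express, was at 38.7 against 13.8 TPM.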
